A study of Mus musculus with 36 samples.

How the data were processed

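Total RNA from mouse liver was hybridized to Illumina MouseWG-6 v2.0 beadchips. Per the labels, RNA was isolated with an AllPrep kit, amplified with an Illumina TotalPrep-96 kit and marked with biotin. Each of 36 arrays held the liver RNA of 1 mouse, with 6 mice for each of 6 diets, and the labels named the diet and the array of every mouse. The mice are called separate samples of a diet here because the series describes 6 mice per diet; p-values rest on the spread between these mice.

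The authors deposited a table of raw values with an intensity and a detection p-value per probe and array. The deposited intensity is a brightness on a linear scale, and its lowest values, far above 0, show no background subtraction. The software that summarized it and the way the deposited detection p-value was computed are not given in the sources used here. The table has 45281 probes with detection p-values and 974 further entries without them, which were taken as control probes and left out of the tests. The authors also deposited a table of processed log2 values for the same 45281 probes. How these were normalized is not given in the sources used here. Every array of that table had a median of 4.402 or 4.403, and its values differed by at most 0.0501 from those computed here from the raw intensities with neqc, so that its scale is log2 and no gene was centred.

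Raw intensities were corrected for background with the detection p-values, quantile normalized and turned into log2 values by neqc of limma 3.58.1 (offset 16) in R 4.3.3, with data.table (version 1.17.8) for reading. A probe was tested when its detection p-value was below 0.05 on at least 6 of the 36 arrays, which kept 17907 probes. Between 31.4% and 34.6% of the probes were detected per array. Differences between diets came from limma, with lmFit on all 36 arrays and a mean for each diet, contrasts and eBayes, two-sided. All diets share an estimate of the spread because each has 6 mice. P-values were adjusted by Benjamini and Hochberg over the probes tested in a comparison, and a probe was called when the adjusted p lay below 0.05. Rises and falls refer to calls, and differences are log2 differences with the standard error of the fit. The median difference over all probes stayed between -0.015 and 0.006 in all 16 comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

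Probes were named from the platform annotation, with symbols updated through the gene identifier or accession in a RefSeq table (assembly GRCm38.p6, used for names only). Of all probes 34885 had 1 gene symbol, 18 had several and 10378 were not listed; of those tested 15409 named 10281 genes, 6 had several symbols and 2492 were not listed. Genes were not named from probes with several symbols. A gene represented by several probes entered the lists through the probe with the highest mean. Of the named genes 34 had several tested probes, and none of their probes were called in opposite directions. A probe detected on no array of a diet has only a bound there. Such a difference is given as at least N-fold, the mean of the brighter diet against the mean of, per array, the higher of the lowest normalized value among detected probes and the dim probe's own value. In the mean of the other berries only the diets without detection took this value. A fold there is no strict bound where another berry on the lower side was detected in only some livers. The median of a list is also given with such genes at their bounds where this moves it.

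The comparisons were high-fat against low-fat, each berry diet against high-fat, açai against the mean of the other berries, each berry diet against low-fat and the pairs of berries. These comparisons, the tests, the alternatives, the rule for named genes and 33 gene lists were fixed before the data were examined. Genes named are the 10 with the largest rise and the 10 with the largest fall among called probes with 1 gene symbol that is not a clone or predicted name and with the same sign on at least 5 of 6 chips (8 per direction for açai against the other berries), and for each list described up to 4 members with the smallest p, and exceptions are stated. Genes shared between lists or comparisons are named as such members. Of the lists, which cover metabolism, stress and immune responses, sex-biased genes and markers of other cell types, 31 had at least 5 tested genes. They were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes, adjusted over the lists of a comparison. The test was repeated with a correlation estimated from the arrays and with fry, which asks whether the genes of a list move on balance in 1 direction. Of 47 calls over the 5 comparisons of high fat with low fat and with the berries, 7 held with an estimated correlation. Cyp2b9 stands in the lists of CAR and PXR targets and of female-biased genes, and Cyp7b1 in those of male-biased genes and bile acids, so that these lists are not independent.

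Each chip held 1 array of each diet, and the number of a mouse within its diet is the number of its chip, so that equal numbers share a chip. This sharing comes from the labels, which name the chip. Deviations from the diet means of arrays on the same chip correlated with a median of 0.107 (range -0.117 to 0.435 over 90 pairs, 45 of them over 0.1), and the own chip correlated best for 24 of 36 arrays. Chip was therefore also fitted as a block, and within a chip a comparison is a single difference, so that the number of chips with the same sign is given. The array position on the chip was the same for all mice of a diet. No pair of arrays had a correlation above 0.991 or shared more than 2 identical raw intensities among all probes, and every array was counted as a sample of its own.

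Comparisons against high-fat share its 6 arrays. Their overlap was set beside groups drawn with no effect against the same arrays, and beside all 10 splits of the high-fat arrays into 3 and 3. Alternatives were other background corrections and normalizations, the deposited log2 values, no filter on dim probes or a detection p-value below 0.01 on all 6 arrays of at least 1 diet, chip as a fixed or random block, only the arrays of the diets compared, other variance models, array weights, 1 probe per gene, stricter thresholds and the arrays of each chip left out. The test was checked on simulated data for high-fat against low-fat, with 200 of 17907 probes changed in 5 runs. It recovered 55.2% of probes changed by a log2 difference of 0.5 and 97.4% of those changed by 1. Among those called 4.6% were false, and it made 0 calls in runs without change. The simulated probes varied independently of each other and held no chip effect, so that these rates need not hold for the real arrays.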

Results

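Gene expression was measured in the livers of 36 male mice aged 20 weeks on Illumina MouseWG-6 v2.0 beadchips, which carry oligonucleotide probes for transcripts of the whole mouse genome. The strain is given as C57BL/6J in the sample labels and as C57BL/6JBomTac in the series design. The mice ate 1 of 6 diets for 13 weeks, with 6 mice per diet: a low-fat diet with 10% of its energy as fat, a high-fat diet with 45%, or the high-fat diet with 20% by weight of freeze-dried lingonberry, blackcurrant, bilberry or açai. Each of the 6 chips held 1 array of every diet, always at the same position for a diet, so that array position and diet cannot be told apart. The median raw intensity of an array lay between 81.2 and 103, and 14240 to 15670 of 45281 probes were detected per array. The median correlation of an array with the others ran from 0.975 to 0.986. Some difference among the 6 diets was called for 1438 of the 17907 probes tested, and the number of arrays limits the precision of every value.

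The comparison of the high-fat with the low-fat diet addressed what dietary fat changed in the liver. Cyp2b9, a cytochrome P450, was at least 10.5-fold higher on high fat (adjusted p = 6.40e-07) and was detected in no low-fat liver and in all 6 high-fat livers. Cyp2b10, the classical target of the nuclear receptor CAR, was at least 4.81-fold higher, and Cyp2b23 at least 2.96-fold. Probes of such closely related genes can share signal, which was not tested. Cyp4a14, a fatty acid hydroxylase controlled by PPARα, rose by a log2 difference of 3.27 ± 0.79 (SE, n = 6 mice per diet, as for every difference here), and Lcn2, which encodes the secreted acute phase protein lipocalin 2, by 2.77 ± 0.67. Gsta1, a glutathione transferase, rose by 2.65 ± 0.49 at one of its probes, while its brighter probe gave 1.25 with an adjusted p of 0.0564, and 0.019 with chip as a block. Lgals1, which encodes galectin-1, rose by 2.10 ± 0.24, and the lipid droplet coat gene Plin4 by 1.82 ± 0.29. The fatty acid binding protein gene Fabp5 was lower on high fat (log2 difference -3.07 ± 0.39), as were Moxd1 (-3.39 ± 0.72), the trefoil factor gene Tff3 (-2.61 ± 0.35) and Igfbp1, a gene that insulin represses (-1.79 ± 0.32). Acacb (acetyl-CoA carboxylase 2), Elovl6 (a fatty acid elongase) and G6pc (the last enzyme of glucose release) were also lower, at -1.72 ± 0.21, -1.41 ± 0.19 and -1.61 ± 0.22. The other genes with the largest differences were Clstn3 (2.02) and Aatk (1.93) among the higher and Adgrf1 (-1.76), Chrna4 (-1.75) and Cib3 (-1.50) among the lower. All 20 of these genes had the sign of their difference on all 6 chips. In total 593 probes were called, 352 of them higher and 241 lower on high fat, and 1049 with chip as a block. Leaving out the arrays of each chip in turn gave 209 to 603. Among the 20 genes above it ended the calls of Cyp2b10 in 4 fits, Cyp4a14 in 3, Lcn2 and Cib3 in 2 each and Moxd1 in 1. A fit on only the arrays of these 2 diets called 276, and there Moxd1 and Cyp4a14 were not called, nor were Cidec, Lpl, Igfbp2, Irs2, Hsd3b5, Nqo1 and Srxn1 of the lists (adjusted p up to 0.135).

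**Figure D1:**
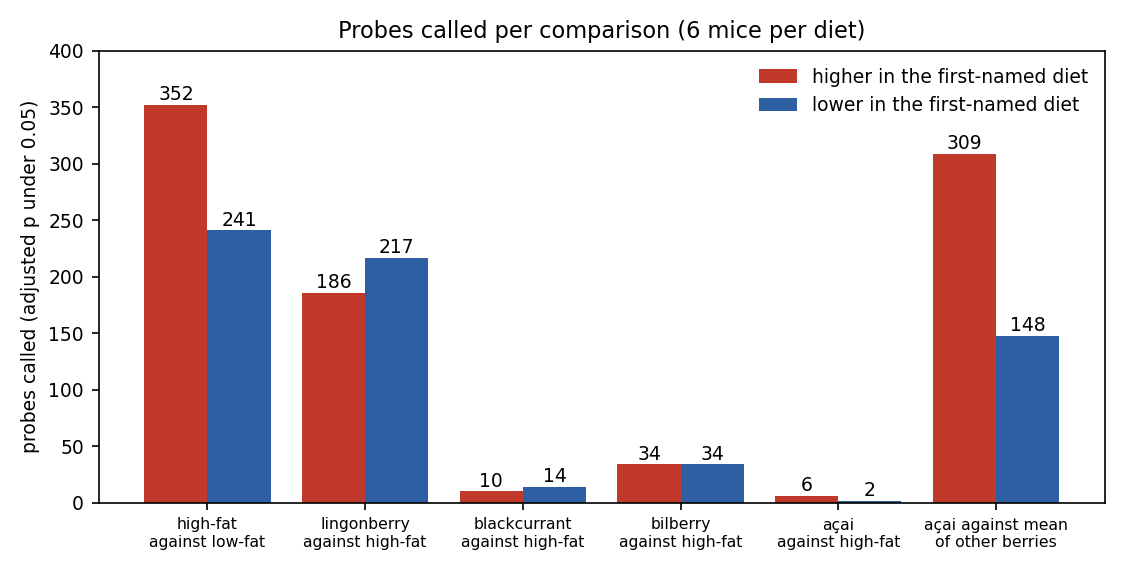
Number of probes called (vertical axis) in each of the 6 comparisons, split into probes higher (red) and lower (blue) in the diet named before "against"; each diet had 6 mice. High-fat against low-fat had the most calls (352 higher and 241 lower), and açai against high-fat the fewest (6 and 2).

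Of the gene lists fixed beforehand, targets of CAR and PXR, the nuclear receptors for foreign compounds, stood highest on high fat. Of its 16 tested genes 7 rose, none fell (11 rose when adjusted over the list alone), and the median log2 difference was 0.52, also with Cyp2b9 and Cyp2b10 at their bounds. The retinal dehydrogenase gene Aldh1a1 rose by 1.12 and the exporter gene Abcc3 by 1.63. The list had an adjusted p = 6.25e-11, and adjusted p = 0.00624 with an estimated correlation. Fatty acid oxidation genes and PPARα targets followed, with 8 of 22 risen, among them Aldh3a2 (1.44), Eci1 (0.66) and Acadm (0.54). Adjusted over the list alone 12 rose (list adjusted p = 2.21e-09, and adjusted p = 0.0351 with an estimated correlation). In fatty acid synthesis 5 of 20 genes fell and none rose, among them Acss2 (-1.38) and Acly (-1.01). Another was Pnpla3, at least 1.58-fold lower on high fat and detected in no high-fat liver. Adjusted over the list alone 7 fell (list adjusted p = 9.12e-11, and adjusted p = 0.0351 with an estimated correlation). A fit on only the arrays of these 2 diets gave adjusted p = 0.051, 0.241 and 0.0263 with an estimated correlation for the CAR and PXR, fatty acid oxidation and fatty acid synthesis lists, with 3 of the oxidation genes risen. Without each chip in turn these calls were kept in 5, 3 and 3 of 6 fits. Among genes more highly expressed in male than in female liver 6 of 18 fell, including Cyp4a12b (-1.14), Elovl3 (-0.93) and Hsd3b5 (-0.93), and 11 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.0598). Of 14 lipid droplet genes and PPARγ targets 4 rose (Pparg 1.65, Cidec 1.68) and Lpl, lipoprotein lipase, fell (-0.70), with 6 risen and 1 fallen adjusted over the list alone. Of 19 genes of glucose production and insulin response 4 fell (Igfbp2 -0.90, Irs2 -0.87), and 5 adjusted over the list alone. Both lists had an adjusted p = 0.0598 with an estimated correlation. Of 21 NRF2 targets and glutathione genes 4 rose, such as Gsta2 (1.27), Srxn1 (0.62) and Nqo1 (0.55), with 6 risen and 2 fallen adjusted over the list alone. Of 17 cholesterol synthesis genes 3 fell, Pmvk (-0.87), Fdps (-0.74) and Tm7sf2 (-0.52), also 3 adjusted over the list alone. The adjusted p was 0.345 with an estimated correlation for both of these lists. Of 16 genes of the urea cycle and amino acid breakdown Cps1 (-0.92) and Ass1 (-0.50) fell, and 3 genes adjusted over the list alone (adjusted p = 0.432 with an estimated correlation). Cytosolic ribosomal proteins, antigen presentation by MHC class II and the endoplasmic reticulum stress response were called lower as lists with no member called (adjusted p = 0.509, 0.465 and 0.465 with an estimated correlation). Without high-fat replicate 1 the ribosomal list was not called (adjusted p = 0.0727). Pancreatic transcripts averaged 4.47 (log2) in high-fat and 4.82 in low-fat livers, where the highest array stood at 6.77. Without background correction Cyp2b10 and Cidec were not called (adjusted p = 0.0604 and 0.0569). With all probes tested Cyp4a14, Lcn2, Cyp2b10, Gsta2, Nqo1, Tm7sf2, Fdps, Lpl, Cidec and Hsd3b5 were not called (adjusted p of 0.0518 to 0.129). Trend and robust variance estimates ended the calls of Cidec and Fdps (adjusted p up to 0.0698), and array weights those of Fdps and Tm7sf2 (up to 0.0576).

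**Figure D2:**
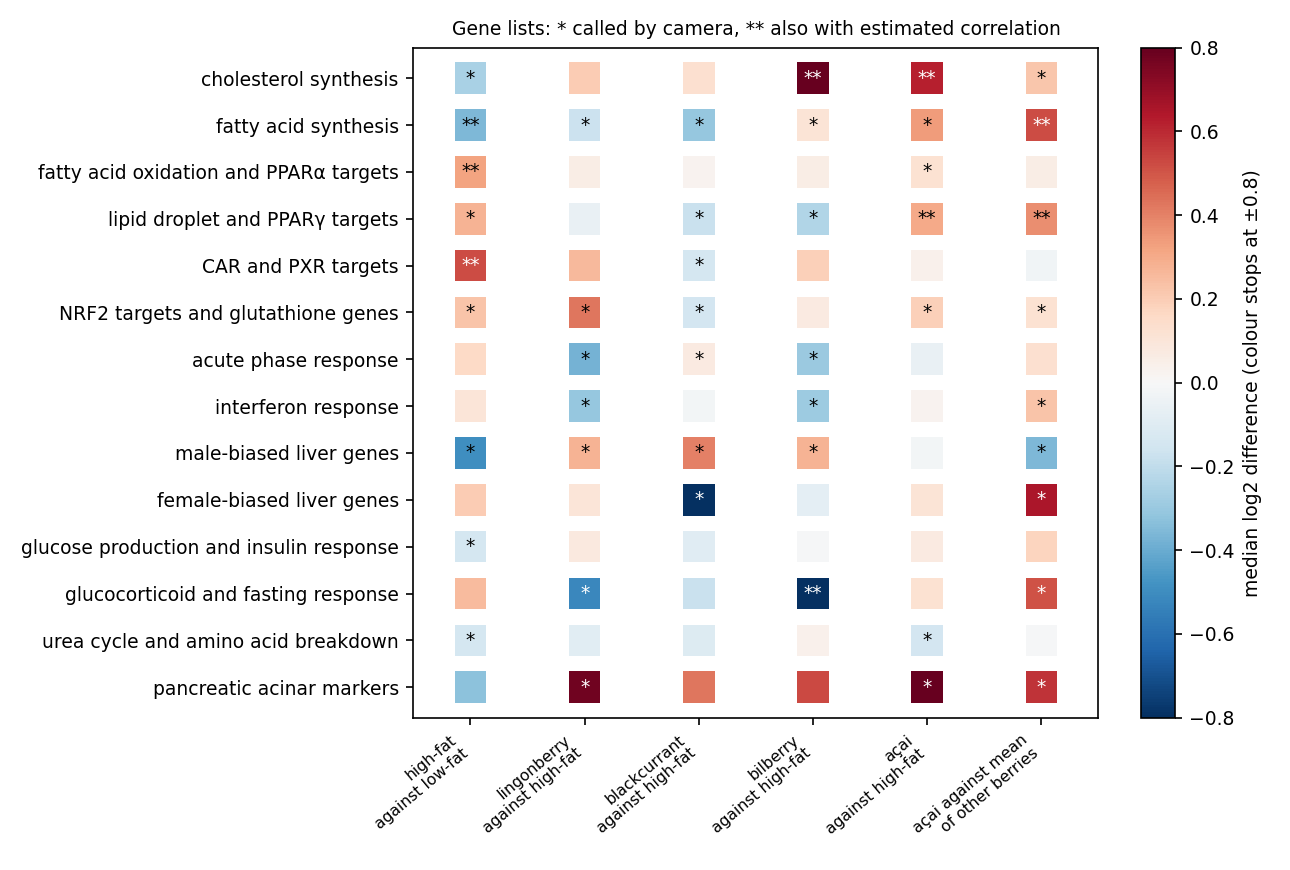
Median log2 difference (colour, red higher and blue lower in the diet named before "against") of the tested genes of 14 fixed lists in each of 6 comparisons, with 6 mice per diet; 1 star marks a list called by camera and 2 stars a list also called with an estimated correlation. Cholesterol synthesis had a median of 0.81 on bilberry and 0.62 on açai, both with 2 stars.

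Lingonberry was compared with high fat alone to ask what this berry changed on the same fat intake. Cyp3a11, the main drug-metabolizing P450 of mouse liver, rose by 2.07 ± 0.22 (adjusted p = 2.22e-07), and Csad, an enzyme of taurine synthesis, by 2.09 ± 0.37. G6pc rose by 1.47 ± 0.22, the steroid dehydrogenase gene Hsd17b6 by 1.38 ± 0.25, the glucuronosyltransferase gene Ugt1a9 by 1.36 ± 0.21 and the prostaglandin transporter gene Slco2a1 by 1.30 ± 0.22. Sox12 (1.30), Igfbp2 (1.11), Akr1c19 (0.98) and Slc39a4 (0.98) were also higher. Lcn2 was lower by -3.46 ± 0.67, Saa1, serum amyloid A1, by -2.98 ± 0.52 and the neutrophil-attracting chemokine gene Cxcl1 by -2.23 ± 0.41. So were the metallothionein genes Mt1 and Mt2 by -2.55 ± 0.60 and -1.88 ± 0.47. Cyp2b9 was lower by -2.98 ± 0.43, the lipogenic regulator gene Thrsp by -1.89 ± 0.45 and Gna14 by -1.69 ± 0.24. Dct (-2.41) and Lrtm1 (-1.91) were lower too. Differences had the same sign on all 6 chips except for Csad, Dct and Thrsp, with 5. Of 21 acute phase genes 4 fell, Lcn2, Saa1, Serpina3n (-0.88) and Saa4 (-0.91). Adjusted over the list alone 10 fell (list adjusted p = 9.93e-06, but adjusted p = 0.536 with an estimated correlation). Of 21 NRF2 targets and glutathione genes 5 rose, such as Gsta4 (0.88), Gstm4 (0.74) and Gstp1 (0.60), and Gstm2 fell (-0.71), with 8 risen with chip as a block, and 11 risen and 1 fallen adjusted over the list alone (adjusted p = 0.536 with an estimated correlation). In the glucocorticoid and fasting list of 14 genes the metallothioneins Mt1 and Mt2 fell and no other member was called, with 3 fallen adjusted over the list alone (adjusted p = 0.536 with an estimated correlation).

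The further lists called on lingonberry were bile acid synthesis and transport, with 1 of 21 risen (Slco1a4, 0.68) and 1 fallen (Cyp2c70, -0.57), 3 risen with chip as a block, and 5 risen and 1 fallen adjusted over the list alone, and male-biased genes with 1 of 18 risen (Keg1, 0.52) and 2 adjusted over the list alone. Fatty acid synthesis followed with 1 of 20 fallen (Thrsp), 3 with chip as a block and 3 adjusted over the list alone, and interferon response with none of 18 called and 2 fallen adjusted over the list alone. With an estimated correlation these 4 lists had adjusted p values of 0.536, 0.592, 0.592 and 0.592, and no list kept its call on lingonberry. Pancreatic acinar markers were called higher as a list with no gene called (median 0.78, or 0.56 with undetected genes at their bounds, adjusted p = 0.67 with an estimated correlation). Their mean was 9.29 in lingonberry replicate 2 against 4.37 to 4.55 in the other 5 lingonberry livers. In total 403 probes were called, 186 higher and 217 lower, and 717 with chip as a block. Leaving out the arrays of each chip in turn gave 123 to 422. Without high-fat replicate 1 Slc39a4, Keg1 and Cyp2c70 lost their calls (adjusted p = 0.0546, 0.0779 and 0.141). Normexp with an offset of 50 ended the call of Mt2 (adjusted p = 0.0764), no background correction those of Mt2 and Dct (0.123 and 0.0542), the pancreatic mean as a covariate that of Cyp2c70 (0.0754), and a fit on only the arrays of the 2 diets those of Cyp2c70 and Thrsp (up to 0.114). Testing all probes ended those of Slc39a4, Mt1, Mt2, Thrsp, Slco1a4, Cyp2c70 and Keg1 (adjusted p of 0.058 to 0.111).

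On blackcurrant fewer genes were called. Cish, a STAT5 target that dampens cytokine and growth hormone signals, rose by 2.36 ± 0.51 (adjusted p = 0.0387), and the male-biased transcript Serpina4-ps1 by 1.68 ± 0.36. The complement gene C8b rose by 0.91 ± 0.19. Igfbp2 rose by 0.89 ± 0.19 at one probe, while its brighter probe, the one given for lingonberry, was not called. Higher as well were the cold-inducible RNA-binding protein gene Cirbp by 0.86 ± 0.19 (adjusted p = 0.0488, and 0.056 with chip as a block), Nudt7 by 0.72 ± 0.14 and Abhd17b by 0.67 ± 0.15. Uck2 was at least 1.15-fold higher and was detected in no high-fat liver. Cyp2b9 was lower by -3.03 ± 0.43 (adjusted p = 0.000505) and Hamp2, a hepcidin gene, by -2.36 ± 0.39 (adjusted p = 0.00444). Lower too were the stearoyl-CoA desaturase gene Scd1 by -1.11 ± 0.23, Lgals1 by -1.22 ± 0.24 and the neurotrophin receptor gene Ntrk2 by -1.22 ± 0.25. Tceal8 (-0.92), Cyp3a25 (-0.83), Gnpda1 (-0.73), Ivns1abp (-0.66) and Cisd1 (-0.59) were also lower. The sign held on 5 of 6 chips for Cish, C8b, Ntrk2, Lgals1 and Scd1 and on all 6 for the others named. Of these 18 genes 15 were given at their brightest tested probe. For the others, Igfbp2 among them, a brighter probe failed the rule for named genes, so that their changes rest on a dimmer probe. Among male-biased genes Serpina4-ps1 was the 1 of 18 that rose, and 7 rose when adjusted over the list alone (median 0.40, adjusted p = 7.33e-09, but adjusted p = 0.0804 with an estimated correlation). Of 7 tested female-biased genes Cyp2b9 fell, and 4 fell when adjusted over the list alone (median -0.97, adjusted p = 0.0804 with an estimated correlation). In fatty acid synthesis Scd1 was the 1 of 20 that fell, with 3 adjusted over the list alone (adjusted p = 0.259 with an estimated correlation). Among 16 CAR and PXR targets Cyp2b9 and Cyp3a25 fell, also 2 adjusted over the list alone (adjusted p = 0.343 with an estimated correlation). Ribosomal proteins and the acute phase list were called higher and NRF2 targets and lipid droplet genes lower with no member called (adjusted p = 0.685, 0.684, 0.565 and 0.363 with an estimated correlation). Of these only Plin4 (-1.22) was called with chip as a block (adjusted p = 0.0346, and 0.0704 without it). Without blackcurrant replicate 4 the acute phase and NRF2 lists were not called (adjusted p = 0.788 and 0.0673). The proteasome list was called with chip as a block (adjusted p = 0.0313) and not without it (0.0577). The acute phase genes varied widely among blackcurrant livers: the mean of Lcn2, Saa1, Saa4 and Serpina3n ran from 9.72 to 13.2. In total 24 probes were called, 10 higher and 14 lower. With only the arrays of the 2 diets compared limma called 0 probes, so that Cyp2b9 and Hamp2 lost their calls too (adjusted p up to 0.342 for the genes named), and 1353 had an unadjusted p below 0.05. Trend and robust variance estimates and array weights each gave 15, and under both Cish, Serpina4-ps1, C8b, Igfbp2, Abhd17b and Uck2 were not called, nor was Scd1 under the first (adjusted p up to 0.0771) or Cirbp and Tceal8 under the second (up to 0.109). Normalization without background correction gave 3 and 14, and normexp with an offset of 50 gave 6 and 14. Under both Cish, Cirbp, Abhd17b, Uck2 and Ntrk2 were not called (adjusted p of 0.0535 to 0.0704), nor were Serpina4-ps1, C8b and Igfbp2 without background correction (0.0512, 0.0512 and 0.0578). Without blackcurrant replicate 4 only the probes of Cyp2b9 and Hamp2 stayed called (2 probes), without high-fat replicate 1 there were 64, and leaving out the arrays of each chip gave 1 to 56. Without high-fat replicate 1 Abhd17b was not called (adjusted p = 0.0563), nor were it, Cirbp and Uck2 without açai replicate 4 (0.0534 for each). With the pancreatic mean as a covariate Cirbp and Uck2 were not called (0.0505 for both), and with all probes tested only Cyp2b9 and Hamp2 were.

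On bilberry genes of cholesterol synthesis rose together against high fat. Of 17 tested genes 10 rose and none fell, and 14 rose when adjusted over the list alone (median 0.81, adjusted p = 3.58e-30, and adjusted p = 0.0049 with an estimated correlation). Nsdhl rose by 1.28 ± 0.22 (adjusted p = 0.00604), Cyp51, lanosterol demethylase, by 1.29 ± 0.24, Sqle, squalene epoxidase, by 1.35 ± 0.32, Msmo1 by 1.17 ± 0.24, Lss by 1.05 ± 0.19 and Fdps by 0.97 ± 0.21. Cish rose by 2.51 ± 0.51 (adjusted p = 0.0147), Csad by 1.79 ± 0.38, G6pc by 1.16 ± 0.22 and the retinol dehydrogenase gene Rdh11 by 0.95 ± 0.19. Lcn2 was lower by -3.12 ± 0.67, Cyp2b9 by -2.94 ± 0.43, Cxcl1 by -2.18 ± 0.41 and Saa1 by -2.18 ± 0.52 (adjusted p = 0.0458, and 0.0592 with chip as a block). The cell cycle inhibitor gene Cdkn1a was lower by -2.15 ± 0.49, Cyp2b23 by -1.67 ± 0.35, the transcriptional repressor gene Bcl6 by -1.65 ± 0.37 and Plin4 by -1.40 ± 0.29. Tcim (-1.38) and Ntrk2 (-1.28) were lower too. The sign of the difference was the same on 6 of 6 chips for all 20 of these genes. Of 25 called genes followed under the alternatives, list members included, 24 were taken at their brightest tested probe. The remaining gene was among the 20 with the largest differences, and its brighter probe failed the rule for named genes. In the glucocorticoid and fasting list Cdkn1a and Tsc22d3, the glucocorticoid-induced leucine zipper (-1.21), fell among 14 genes and 7 fell when adjusted over the list alone. Mt1 gave -2.42 with an adjusted p of 0.0607 and Mt2 -1.94 with 0.0526 (list median -0.80, adjusted p = 8.33e-09, and adjusted p = 0.0392 with an estimated correlation). Without each chip in turn the call with an estimated correlation was kept in 6 of 6 fits for cholesterol synthesis, with 2 to 10 genes risen, and in 2 of 6 for the glucocorticoid and fasting list (adjusted p up to 0.15). Of 21 acute phase genes 3 fell, Lcn2, Saa1 and Serpina3n (-0.79), and 4 adjusted over the list alone (adjusted p = 0.273 with an estimated correlation). These 3 genes lost their calls in 3, 6 and 6 of the fits that left out the arrays of a chip or a single array.

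Of the other lists called on bilberry, male-biased genes had none of 18 called, with Keg1 (0.55) called with chip as a block (adjusted p = 0.0437), and 6 risen adjusted over the list alone. Interferon response had Usp18 fallen (-0.85, adjusted p = 0.0496, and 0.0633 with chip as a block) among 18, also 1 adjusted over the list alone. Likewise lipid droplet genes had Plin4 fallen among 14 and 3 adjusted over the list alone. Fatty acid synthesis had Acss2, which makes acetyl-CoA from acetate, risen (0.91) among 20 and 2 adjusted over the list alone, and bile acid synthesis and transport none of 21 called and 2 risen adjusted over the list alone. In the last of these Cyp8b1 (0.74) was called with chip as a block (adjusted p = 0.0435). With an estimated correlation these 5 lists had adjusted p values of 0.15, 0.5, 0.273, 0.585 and 0.5, in the order male-biased, interferon, lipid droplet, fatty acid synthesis and bile acid. Without high-fat replicate 1 the fatty acid synthesis list was not called (adjusted p = 0.0778). In total 68 probes were called, 34 in each direction, and 109 with chip as a block. A fit on only the arrays of the 2 diets called 110, without Cyp2b23, Plin4 and Ntrk2 (adjusted p up to 0.0857), and array weights gave 141. Trend and robust variance estimates ended the calls of Sqle, Fdps, Csad, Lcn2, Saa1, Serpina3n, Cdkn1a, Tsc22d3, Bcl6, Tcim and Usp18 (adjusted p up to 0.101). Leaving out the arrays of each chip gave 10 to 49, and without high-fat replicate 1 Saa1, Serpina3n and Usp18 lost their calls (adjusted p = 0.0765, 0.0886 and 0.0783). Normexp with an offset of 50 ended the calls of Sqle, Lcn2, Saa1, Cdkn1a, Cyp2b23 and Usp18 (adjusted p of 0.0518 to 0.0843). No background correction ended these and those of Bcl6 and Serpina3n (0.0548 to 0.127). With the pancreatic mean as a covariate Sqle, Saa1, Serpina3n and Usp18 were not called (0.0547 to 0.0596), nor were Sqle and Usp18 without açai replicate 4 (0.0504 for both). When all probes were tested only Nsdhl, Cyp51, Lss and Cyp2b9 stayed called among the 20 genes with the largest differences, and Tsc22d3, Serpina3n, Acss2 and Usp18 lost their calls too.

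On açai few single genes differed from high fat alone. Cidea, which promotes the fusion of lipid droplets, rose by 2.39 ± 0.32 (adjusted p = 6.73e-05), Osbpl3, a lipid-binding protein gene, by 1.27 ± 0.21, the actin regulator kinase gene Limk1 by 1.16 ± 0.14 and Pparg, the fat-storage regulator PPARγ, by 0.98 ± 0.17 at one probe (the brighter Pparg probe gave 0.82 with an adjusted p of 0.202). Cyp8b1, which directs bile acid synthesis to cholic acid, rose by 0.89 ± 0.18 and Niban2 by 0.72 ± 0.14, while Cyp2c70, which makes muricholic acids, was lower by -0.86 ± 0.16 and the hepcidin gene Hamp by -0.52 ± 0.10. These were the 8 probes called, 6 higher and 2 lower, each with its sign on 6 of 6 chips. With only the arrays of açai and high fat limma called 0 probes (adjusted p up to 0.219 for these 8), and 1114 had an unadjusted p below 0.05. Chip as a block gave 22, as 20 higher and 2 lower. Normexp with an offset of 50 and normalization without background correction each gave 22 as well, also 20 and 2. Without high-fat replicate 1 the 3 of Cidea, Osbpl3 and Limk1 were called, with adjusted p of 0.0715 for Pparg, Niban2 and Cyp2c70, 0.0803 for Cyp8b1 and 0.0966 for Hamp. Leaving out the arrays of each chip gave 2 to 19. Without açai replicate 4 Cyp8b1, Niban2 and Hamp were not called (adjusted p = 0.0659, 0.0672 and 0.0568). Neither were Cyp8b1 and Niban2 with all probes tested (0.12 and 0.06).

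Cholesterol synthesis genes were higher on açai as a list: none of 17 was called alone, and 14 rose when adjusted over the list alone (median 0.62, adjusted p = 1.86e-21, and adjusted p = 0.016 with an estimated correlation), with Fdps at 0.94, Sqle at 1.31 and Nsdhl at 0.87. Lipid droplet genes and PPARγ targets had Cidea risen among 14 and 3 risen adjusted over the list alone, with Cidec at 1.99 and an adjusted p of 0.0874 (list adjusted p = 3.55e-08, and adjusted p = 0.0142 with an estimated correlation). A fit on only the açai and high-fat arrays ended both of these list calls with an estimated correlation (adjusted p = 0.188 for each), and without the arrays of each chip they held in 3 and 4 of 6 fits. Fatty acid synthesis had none of 20 called and 8 risen and 1 fallen adjusted over the list alone, with Acacb at 0.87 and Me1 at 0.82 (adjusted p = 2.45e-09, but adjusted p = 0.062 with an estimated correlation). NRF2 targets, fatty acid oxidation, macrophage markers, MHC class II and cell cycle were called higher and ribosomal proteins and the urea cycle lower with no member called, also over the list alone (adjusted p of 0.181, 0.564, 0.564, 0.631, 0.564, 0.631 and 0.605 with an estimated correlation). Without açai replicate 4 macrophage markers, MHC class II, cell cycle and the urea cycle were not called (adjusted p = 0.134, 0.819, 0.134 and 0.0612), nor were fatty acid oxidation, cell cycle and the urea cycle without high-fat replicate 1 (0.0808, 0.124 and 0.239). The MHC class II genes averaged 9.55 in açai replicate 4 against 7.31 to 7.68 in the other açai livers. Pancreatic acinar markers were called higher as a list with no gene called (median 1.19, or 1.12 with undetected genes at their bounds, adjusted p = 0.564 with an estimated correlation). Their mean per array ran from 4.40 to 8.73 on açai, with a median of 4.44. With this mean as a covariate 17 probes were called on açai.

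Açai was set against the mean of the other 3 berries, a difference that holds no high-fat array, although these arrays share in the estimate of the spread. Cidea was 9.88-fold higher on açai (adjusted p = 5.66e-11) with only blackcurrant at the value for undetected diets, so that this is no strict bound. It was detected in all 6 açai livers, in 1 lingonberry and 1 bilberry liver and in no blackcurrant liver. Its relative Cidec was higher by 3.13 ± 0.38, Cyp2b9 by 2.97 ± 0.35 and Lcn2 by 2.42 ± 0.55. The Lcn2 difference came from lingonberry and bilberry (-3.46 and -3.12 against high fat), while blackcurrant (-0.03) was close to açai (0.21). Cyp2b10 was higher by 2.28 ± 0.53, Plin4 by 1.93 ± 0.23, Cyp2b23 by 1.88 ± 0.29 and the apolipoprotein gene Apoa4 by 1.78 ± 0.27. The vasopressin receptor gene Avpr1a was lower by -1.69 ± 0.21, Osgin1 by -1.67 ± 0.36, the male-biased Hsd3b5 by -1.61 ± 0.20 and Enho, which encodes the secreted peptide adropin, by -1.60 ± 0.21. Foxq1 (-1.22), Id2 (-1.14) and Phlda1 (-1.09) were also lower, and Dnaic1, detected in no açai liver, was at least 1.72-fold lower. The sign was the same on 6 of 6 chips for these genes except Phlda1, with 5. Of 20 fatty acid synthesis genes 8 were higher on açai, such as Acacb (1.25), Elovl5 (0.66) and Acly (0.58), and Mlxipl, the carbohydrate-sensing regulator ChREBP, was lower (-0.52). Adjusted over the list alone 14 were higher and 1 lower (list adjusted p = 1.38e-11, and adjusted p = 0.0342 with an estimated correlation). Of 14 lipid droplet genes 5 were higher, Cidea, Cidec, Plin4, Apoa4 and the fatty acid transporter gene Cd36 (0.48), and 6 adjusted over the list alone (adjusted p = 3.68e-11, and adjusted p = 0.00184 with an estimated correlation). Without the high-fat and low-fat arrays the fatty acid synthesis list lost its call with an estimated correlation (adjusted p = 0.0865), and it kept it in 1 of 6 fits without the arrays of a chip (adjusted p up to 0.106). The other lists called lost their calls with an estimated correlation. Among them were the glucocorticoid and fasting list with 3 of 14 higher (Mt2 1.54, Cdkn1a 1.55, Mt1 1.75) and 8 adjusted over the list alone, and female-biased genes with Cyp2b9 higher among 7, 2 with chip as a block and 2 adjusted over the list alone (adjusted p = 0.0754 with an estimated correlation for both). Cell cycle genes had 4 of 14 higher (Mcm5 0.66, Rrm2 0.52) and 5 adjusted over the list alone (adjusted p = 0.151 with an estimated correlation). Male-biased genes had 2 of 18 lower (Hsd3b5 and Cyp7b1, -0.72) and 4 adjusted over the list alone (adjusted p = 0.172 with an estimated correlation). Cholesterol synthesis had Fdps (0.70) higher among 17, also 1 adjusted over the list alone. By its differences from high fat given above, Fdps was not higher on açai than on bilberry. NRF2 targets had 3 higher (Gsta2 0.90, Gstm2 0.72, Srxn1 0.53) and Gstp1 lower (-0.46) among 21, with 4 higher and 1 lower adjusted over the list alone. Bile acid synthesis and transport had Cyp8b1 (0.65) higher and Cyp2c70 (-0.71), Cyp7b1 and Slc10a1 (-0.50) lower among 21, with 1 higher and 4 lower adjusted over the list alone. These 3 lists had an adjusted p = 0.54 with an estimated correlation. Stellate cell and matrix genes had Col4a1 (0.57) and Col3a1 (0.76) higher among 17, with 3 adjusted over the list alone (adjusted p = 0.471 with an estimated correlation). Macrophage markers had Gpnmb higher among 11, also 1 adjusted over the list alone (adjusted p = 0.581 with an estimated correlation). The difference was 1.97-fold with only lingonberry at the value for undetected diets, again no strict bound. Gpnmb was detected in all 6 açai livers and in no lingonberry, 2 blackcurrant and 1 bilberry livers. Interferon response was called higher and ribosomal proteins lower with no member called, and 2 ribosomal genes lower adjusted over the list alone (adjusted p = 0.616 and 0.54 with an estimated correlation). With chip as a block Rpl24 (-0.26) and Rps14 (-0.20) were called (adjusted p = 0.0343 and 0.0246). The interferon genes averaged 8.61 in açai replicate 4 against 7.26 to 7.49 in the other açai livers. Pancreatic acinar markers were called higher as a list (median 0.58, adjusted p = 0.038, but 0.0518 with chip as a block and adjusted p = 0.72 with an estimated correlation), with no gene called. In total 457 probes were called, 309 higher and 148 lower, and 756 with chip as a block. Leaving out the arrays of each chip gave 204 to 403. The lists of NRF2 targets, stellate cell genes, macrophage markers, interferon response and pancreatic markers were not called without açai replicate 4 (adjusted p = 0.157, 0.0664, 0.385, 0.793 and 0.419). Without açai replicate 4 Foxq1, Phlda1, Cyp7b1, Gsta2, Col3a1 and Mcm4, a further called cell cycle gene, were not called (adjusted p = 0.0752, 0.103, 0.0618, 0.122, 0.129 and 0.0775), and without high-fat replicate 1 Col3a1 was not (0.0524). Normexp with an offset of 50 ended the call of Mt2 (0.0643), and no background correction those of Lcn2, Foxq1, Phlda1, Mt2, Cdkn1a, Mt1 and Col3a1 (0.0536 to 0.103). Testing all probes ended those of Foxq1, Id2, Phlda1, Gsta2, Cyp7b1, Fdps, Mt2, Cdkn1a, Mt1 and Col3a1 (0.0543 to 0.14), the pancreatic mean as a covariate that of Gsta2 (0.0615), and trend and robust variance estimates those of Foxq1, Phlda1, Mt1, Gsta2 and Col3a1 (up to 0.0828).

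**Figure D3:**
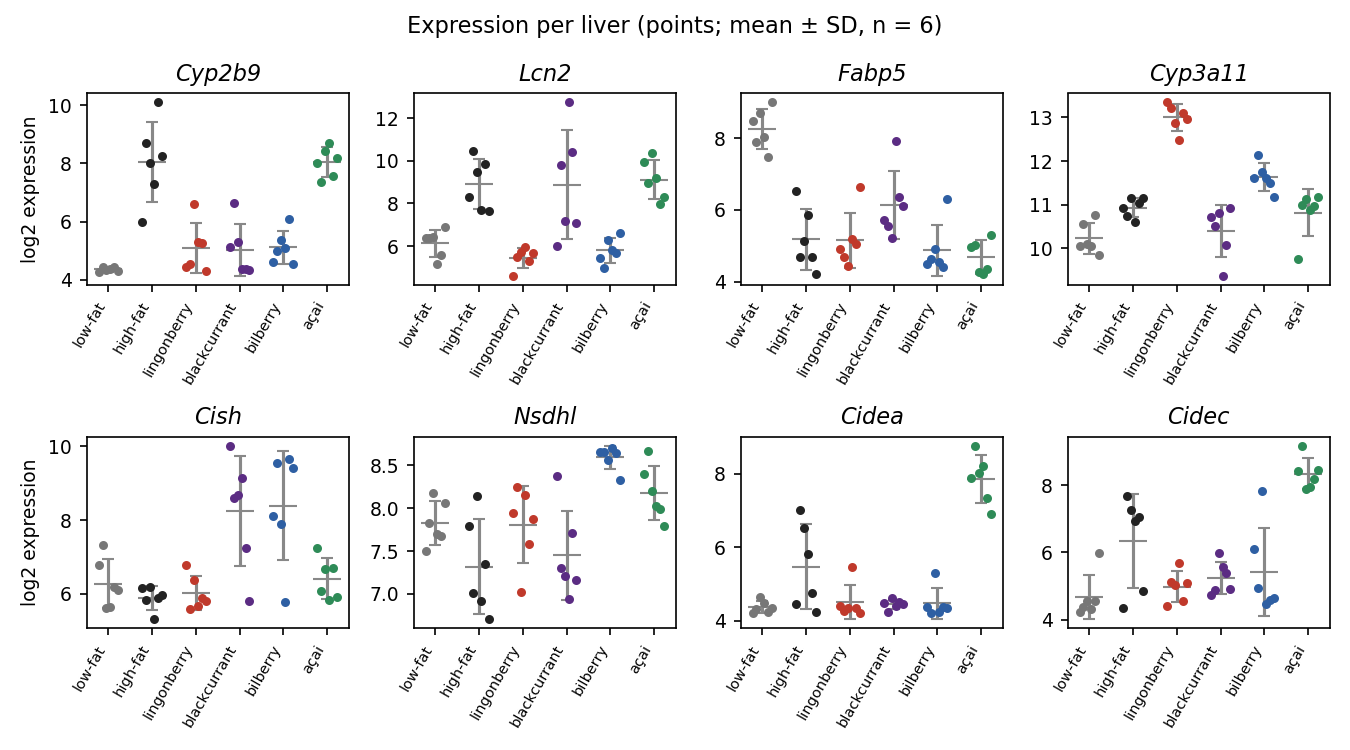
Log2 expression of 8 genes (vertical axis) in each liver (points) of the 6 diets (horizontal axis), with the mean and SD of 6 mice per diet as grey lines. Cyp2b9 averaged 8.05 on high fat and 8.04 on açai and 5.02 to 5.11 on the other berries, and Cidea and Cidec were highest on açai.

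The pairs of berries differed as well. Açai differed from lingonberry in 599 probes, from blackcurrant in 316 and from bilberry in 138, while lingonberry differed from blackcurrant in 176 and from bilberry in 44, and blackcurrant from bilberry in 38. With chip as a block these 6 counts were 940, 571, 239, 332, 99 and 76, and with array weights 840, 319, 270, 188, 145 and 70. They were 599, 196, 193, 92, 51 and 1 with only the arrays of the pair, and 413, 213, 88, 108, 14 and 25 with all probes tested. Without each chip in turn they were 281 to 544, 105 to 288, 71 to 152, 40 to 212, 9 to 52 and 2 to 82. Without blackcurrant replicate 4 the pairs of blackcurrant with açai, lingonberry and bilberry had 169, 94 and 23. Among the calls against high fat, Cyp2b9, Ntrk2 and a probe with no listed gene were called lower on lingonberry, blackcurrant and bilberry, 41 probes were called in 2 berry diets and 412 in only 1. Lingonberry and bilberry had 33 calls in the same direction, including Lcn2, Saa1, Cxcl1 and Cyp2b9 among the lower and Csad and G6pc among the higher. Independent lists of these sizes would share 0.77. Unchanged groups, set against a shared group drawn from all arrays, had 0.06 and 0.16 calls on average. The 0 they shared thus gives no baseline for lists of these sizes. The covariance of the lingonberry and bilberry log2 differences across genes, which are not independent replicates, was 0.0282. Unchanged groups sharing a drawn reference group gave 0.0118. With the high-fat arrays split 3 and 3 so that none was shared, the covariance for lingonberry and bilberry was 0.0172. With that split, lists of 143.9 and 15.9 probes on average shared 1.5 (0 to 5), where independent lists would share 0.046.

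The low-fat livers served as reference for how far each berry diet moved the genes that high fat had changed. Against low fat, 587 probes were called on lingonberry, 413 on blackcurrant, 288 on bilberry and 1158 on açai, 1629 in at least 1 of them, and 2596 in at least 1 with chip as a block. Fitted on the arrays of the 2 diets alone, the 4 counts were 421, 105, 241 and 858, and with all probes tested 438, 250, 205 and 868. Fits that left out each chip gave 359 to 485, 172 to 424, 142 to 303 and 707 to 1049, and without blackcurrant replicate 4 there were 258 on blackcurrant. Of the 593 probes changed by high fat, 89 were called back towards low fat on lingonberry, 11 on blackcurrant, 24 on bilberry and none on açai, 102 in at least 1 berry diet, and 6 were called further away on lingonberry and 4 on açai. The count of 102 was 226 with chip as a block, 167 with array weights, 49 with all probes tested and 46 with only the arrays of the diets compared (36 on lingonberry, 22 on bilberry and none on blackcurrant, where limma then called 0 probes against high fat and 1353 had an unadjusted p below 0.05). Fits without the arrays of each chip gave 13 (without chip 5) to 134, as 12 to 128 on lingonberry, 1 to 23 on blackcurrant and 5 to 22 on bilberry. Without high-fat replicate 1 these 3 berries had 111, 38 and 38, and without blackcurrant replicate 4 blackcurrant had 1. Cyp2b9 and G6pc were among those that moved back on lingonberry and bilberry, and Cidea was among those that moved further on açai. Because both sides of this count use the high-fat arrays, these were split 3 and 3 in all 10 ways and both roles. Of the 249.3 probes then called on average between high fat and low fat, 69.5% (58.6% to 81.7% over the splits) had shifted towards low fat on lingonberry, 71.5% (62.4% to 79.2%) on blackcurrant and 67.5% (52.4% to 83%) on bilberry. On açai 29.7% (18.7% to 45.2%) had done so. The covariance across genes of the berry and the low-fat differences from high fat was 0.0264 for lingonberry and 0.0218 for blackcurrant. It was 0.0243 for bilberry and 0.0019 for açai. Unchanged groups sharing a drawn reference group gave 0.0113 to 0.0121. With the split high-fat arrays the covariance of the 4 berry diets was 0.0154, 0.0108, 0.0132 and -0.0091, in the same order.

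**Figure D4:**
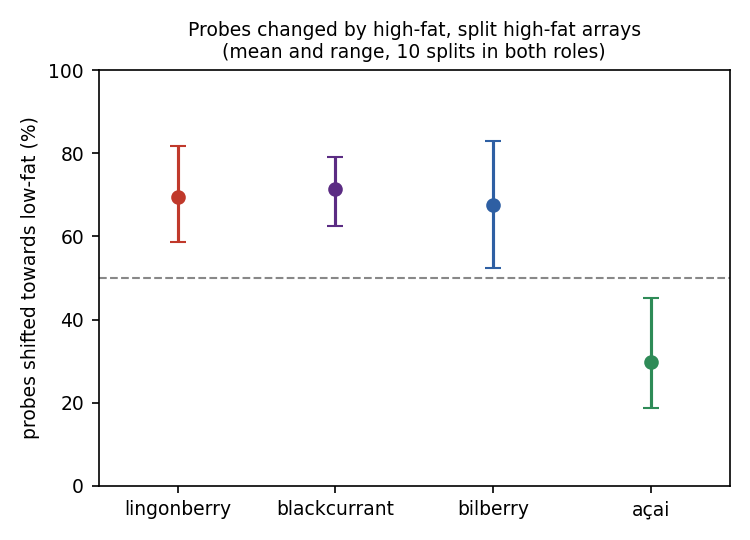
Percentage of the probes changed by high fat whose level shifted towards low fat (vertical axis) in each berry diet, with the high-fat arrays split 3 and 3 so that no array entered both differences; points are means and bars the lowest and highest of 10 splits in both roles. The means were 69.5%, 71.5% and 67.5% for lingonberry, blackcurrant and bilberry and 29.7% for açai, and the dashed line marks equal shares in both directions.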

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

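The tests of the pancreatic and the acute phase genes and the splits that keep the chips apart were chosen after the results they bear on were seen, while the count of random splits and the test of Cish with Socs2 and Bcl6 were written before. An earlier form of the acute phase test used only the 4 genes called and was set aside, since they had been chosen for the difference it measured.

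Pairs of berry diets differed in their effect on the high-fat liver. By tests of the difference, açai differed from the mean of the other berries in 457 probes, from lingonberry in 599, from blackcurrant in 316 and from bilberry in 138. Lingonberry differed from blackcurrant in 176, lingonberry from bilberry in 44 and blackcurrant from bilberry in 38. With only the arrays compared these 7 counts were 523, 599, 196, 193, 92, 51 and 1, so that few differences between blackcurrant and bilberry were called by that fit. For the 6 comparisons the diet labels were exchanged in 100 splits of the arrays, the real one included. In açai against the other berries all berry labels were exchanged, so that the test there asks whether all berries were alike. It does not ask whether açai equals the mean of the others, which also differed among themselves. As many calls as the real split came from 1 of 100 for high-fat against low-fat (593 against at most 47 in the others), lingonberry (403 against 61), bilberry (68 against 43) and açai against the other berries (457 against 6). They came from 2 of 100 for blackcurrant (24 against 41) and from 3 of 100 for açai against high-fat (8 against 14). In this test, which ignores the shared chips, chance is an unlikely source of the counts that no other split reached. It was not excluded for açai against high-fat, where another split called 14 probes against 8. Nor was it excluded for blackcurrant, which the splits within chips left open too. An earlier draw of 100 splits was set aside because it dealt the remaining arrays in a fixed turn in açai against the other berries, which leaves the 5 other comparisons untouched. It had highest other counts of 314, 47, 4, 17, 14 and 16 in the order high-fat, lingonberry, blackcurrant, bilberry, açai and açai against the other berries. Among the 32 splits that part the 2 arrays of every chip as the real one does, the highest other counts were 117, 91, 44, 1 and 2 for high-fat, lingonberry, blackcurrant, bilberry and açai. For blackcurrant 2 of these 32 gave as many calls, also with chip as a block (94 against 34), so that chance was not excluded there.

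Pancreatic acinar transcripts were high in a few livers of several diets. The list mean was 9.29 in lingonberry replicate 2, 7.77 in bilberry replicate 2 and 6.91 in blackcurrant replicate 3, each far from the other livers of its diet, and 4.64 in high-fat replicate 2 against at most 4.48. Cela2a averaged 5.03 on high fat, where 4 of 6 livers had it detected, and 6.43 on açai, and Clps averaged 4.53, detected in 2 of 6, and 5.93. Pancreatic tissue taken with the liver is a candidate source: after removing diet means the 15 markers had a median pairwise correlation of 0.979 over the 36 arrays (lowest 0.928), as tissue with fixed proportions would give. An effect of açai itself on these genes cannot be told apart from it. The açai mean was 1.15 above the high-fat mean with an exact permutation p of 0.392 (two-sided, 6 against 6). Without its highest array it was still 4.99 against 4.47, or 4.44 without the highest high-fat array. The medians were 4.44 on açai and 4.45 on high fat, so that no shift common to the açai livers was seen.

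Acute phase genes were lower on lingonberry and bilberry than on high fat, with 4 and 3 of 21 called and adjusted p = 0.536 and 0.273 for the list with an estimated correlation. The tables argue against a few high-fat livers with high values as the whole cause, since in the mean of all 21 genes 6 of 6 high-fat livers (10.27 to 10.96) lay above the highest of the 12 lingonberry and bilberry livers (10.18), the lowest of them only narrowly, although that mean holds the called genes and over the 17 genes not called 5 of 6 did, with high-fat livers (10.2 to 10.74) overlapping the others (9.99 to 10.31). Fewer neutrophils remain possible and cannot be told apart from a change in hepatocytes: S100a8 and S100a9, abundant in neutrophils, gave a mean of -0.82 on lingonberry (larger SE 0.43, adjusted p up to 0.392) and -0.52 on bilberry (up to 0.871), with S100a8 at 8.53 on high fat. The other neutrophil markers tested, Retnlg, Ltf and Elane, differed little and were not called. They gave -0.18, -0.1 and -0.16 on lingonberry and -0.06, -0.04 and -0.05 on bilberry. A different time of day at killing was not settled. The clock list was not called (fry mixed adjusted p of 0.89 on lingonberry and 1 on bilberry). The clock genes with the largest difference were Per2 on lingonberry (-1.05 ± 0.30, adjusted p = 0.0569, and 0.0388 with chip as a block) and Ciart on bilberry (-1.11 ± 0.44, adjusted p = 0.447). An effect of the 2 berries on the acute phase response stays an open hypothesis.

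Cish rose and Bcl6 fell on bilberry, each with the same sign on 6 of 6 chips. Each chip held 1 array of every diet, so that a difference between chips enters both diets alike, while array position cannot be told apart from diet. Without background correction Bcl6 was not called (adjusted p = 0.0548). In the fits that left out the arrays of a chip or a single array, Bcl6 lost its call in 5 and Cish in 2. A difference between livers in growth hormone signalling through STAT5, which induces Cish and Socs2 and represses Bcl6, may contribute but cannot be told apart from an effect of bilberry: over 36 livers after removing diet means Cish and Socs2 had r = 0.28 (permutation p = 0.101, rho 0.30 with p = 0.0804, 0.23 without the 2 livers farthest from the median, 0.32 within chips). Cish and Bcl6 had r = -0.60 (permutation p = 0.00019, adjusted 0.00038 over 2 relations, rho -0.43 with p = 0.00914 and adjusted 0.0183), which rested in part on 2 livers, since without them r was -0.27, and within chips it was -0.51.

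Single livers stood apart from the 5 others of their diet in 29 of 333 groups examined. About 16.6 would be expected by chance at 1 in 20 if the groups were independent and their values normally distributed. The groups reuse the same livers, and some values lie near the detection limit, so that the excess was not tested. Median raw intensity was low for its diet in high-fat replicate 3 (81.24 against 93.19 to 99.88) and açai replicate 3 (84.02 against 92.34 to 95.45). The arrays of chip 3 had the lowest intensity of every diet except lingonberry. The median correlation with other arrays was low in blackcurrant replicate 4 (0.9748). Among list means, cholesterol synthesis was low in low-fat replicate 2 (8.40), the acute phase list high in lingonberry replicate 4 (10.18), the lipid droplet list high in bilberry replicate 3 (8.02), and MHC class II and interferon genes high in açai replicate 4 (9.55 and 8.61). High-fat replicate 1 was apart in Moxd1 (8.16), Tff3 (7.94), Adgrf1 (5.11), C8b (11.14) and Cyp2c70 (13.20). Lingonberry replicate 4 was apart in Dct (8.14) and Cidea (5.47), and lingonberry replicate 6 in Cxcl1 (8.04). Blackcurrant replicate 6 was apart in Ntrk2 (4.89) and Hsd3b5 (11.76) and replicate 4 in Ivns1abp (8.36). Bilberry replicate 3 was apart in Cdkn1a (6.58) and Cidea (5.30), replicate 4 in Bcl6 (9.67) and replicate 6 in Nsdhl (8.33). Gsta1 was high in low-fat replicate 5 (6.82) and Limk1 in high-fat replicate 2 (5.65).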

How the results depend on the processing

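The alternatives without single arrays (blackcurrant replicate 4, high-fat replicate 1 and açai replicate 4) and with the pancreatic mean as a covariate, and the list tests with an estimated correlation on fewer arrays, were chosen after seeing the data; the others were planned. Of 195 gene and comparison pairs called, none changed sign under any alternative and 166 stayed called under all normalizations and the chip block, but 122 lost their call under at least 1 of the alternatives set beforehand that left out no chip, stricter thresholds included. Leaving out the arrays of a chip ended 48 to 101 of these calls (101 without chip 2, 87 without chip 5), and a single array 16 (blackcurrant replicate 4), 13 (high-fat replicate 1) and 15 (açai replicate 4). Among these pairs the chip block ended the calls of Cirbp on blackcurrant and of Saa1 and Usp18 on bilberry, and among the lists of the 6 comparisons it changed those of the proteasome on blackcurrant and of pancreatic markers on açai against the other berries. It changed no other list call there, and it gave a call to 22 of the 221 pairs without one. The number of the 195 that lost their call was 14 with normexp and an offset of 50, 29 without background correction, 78 with all probes tested, 47 with only the arrays of the diets compared, 29 with trend and robust, 10 with array weights, 25 at a 1.5-fold change, 104 at an adjusted p below 0.01 and 10 with the pancreatic covariate. The balance of the lingonberry calls was 186 higher and 217 lower, 286 and 278 with array weights, and 65 and 58 without the arrays of chip 2. Counts are in probes, in the order high-fat against low-fat, lingonberry, blackcurrant, bilberry and açai against high-fat, açai against the other berries, the return towards low-fat and the union of the berry diets against low-fat. Alternatives that moved a count by less than 1.5 times are not listed. With the deposited log2 values no count moved by that much. These lay within 0.0501 of the values used here, so that they are hardly a separate normalization.

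With chip as a block the counts were 1049 for high-fat, 717 for lingonberry, 109 for bilberry, 22 for açai, 756 for açai against the other berries, 226 for the return and 2596 against low-fat, and with chip as a random block 917, 666, 63 for blackcurrant, 117, 34, 717 and 205 for the return. The block takes chip differences out of the spread, and its further effect was not tested. Normexp with an offset of 50 and no background correction each gave 22 for açai, and a detection p below 0.01 on all 6 arrays of at least 1 diet gave 18. Testing all probes gave 372 for high-fat, 253 for lingonberry, 2 for blackcurrant, 14 for bilberry and 49 for the return, as more probes enter the adjustment. With only the arrays of the diets compared, which leaves fewer arrays to estimate the spread, limma gave 276 for high-fat, 0 for blackcurrant, 110 for bilberry, 0 for açai and 46 for the return. On blackcurrant and açai 1353 and 1114 probes then had an unadjusted p below 0.05, and 1553 and 1086 with all arrays. eBayes with trend and robust gave 15 for blackcurrant and 16 for açai. Array weights gave 15 for blackcurrant, 141 for bilberry, 25 for açai and 167 for the return; the cause was not tested for these and for the normalizations. A change of at least 1.5-fold left 288 for high-fat, 227 for lingonberry, 190 for açai against the other berries, 51 for the return and 780 against low-fat, and an adjusted p below 0.01 left 233, 126, 2, 12, 3, 185, 20 and 751 in the order above, both by construction. With the pancreatic mean as a covariate açai had 17; the cause was not tested. Of 47 list calls 7 held in camera with an estimated correlation, which alone sets that test apart. fry, which tests a list against no change and not against other genes, called 14; the cause was not tested.

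Leaving out arrays, of a chip or single, gave 209 to 675 for high-fat, 123 to 440 for lingonberry, 1 to 64 for blackcurrant, 10 to 76 for bilberry, 2 to 19 for açai, 204 to 471 for açai against the other berries, 13 to 137 for the return and 1017 to 1641 against low-fat. Without blackcurrant replicate 4 there were 2 for blackcurrant, and without high-fat replicate 1 there were 64 for blackcurrant and 3 for açai. Probes not above background are limited to bounds, and about 33.5% of probes were detected on a median array.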

Other observations

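The lists and comparisons of this part were fixed beforehand, but which of them are described was decided after their values were seen, and the test of the control probes and the values of lists without single livers, without the arrays of a chip or with only the arrays compared were chosen after the main results.

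Set against each other, the berry diets differed in genes of several lists. Cholesterol synthesis genes were lower on lingonberry than on bilberry, with 3 of 17 called, 5 with chip as a block and 13 adjusted over the list alone (median -0.64, adjusted p = 0.039 with an estimated correlation). They were also lower on blackcurrant than on bilberry, with 4 called and 14 adjusted over the list alone (median -0.70, adjusted p = 0.0206 with an estimated correlation). Acute phase genes were lower on lingonberry than on blackcurrant, with 8 of 21 called and 11 adjusted over the list alone (median -0.64, adjusted p = 0.0427 with an estimated correlation). Without blackcurrant replicate 4, whose mean of this list was 12.2 against at most 11.2 in the other blackcurrant livers, 4 were called and the list lost that call (median -0.38, adjusted p = 0.0539 with an estimated correlation). They were higher on blackcurrant than on bilberry, with 1 called, 2 with chip as a block and 10 adjusted over the list alone (median 0.49, adjusted p = 0.034 with an estimated correlation). Without blackcurrant replicate 4 limma called none of them, and 9 adjusted over the list alone (median 0.34, adjusted p = 0.04 with an estimated correlation). NRF2 targets and glutathione genes were higher on lingonberry than on blackcurrant, with 8 of 21 called and 13 adjusted over the list alone (median 0.51, or 0.46 with undetected genes at their bounds, adjusted p = 0.0111 with an estimated correlation), and 5 were called without blackcurrant replicate 4. Fatty acid synthesis genes were higher on açai than on blackcurrant, with 10 of 20 called higher, 11 higher and 1 lower with chip as a block, and 14 higher and 1 lower adjusted over the list alone (median 0.70, adjusted p = 0.00569 with an estimated correlation). Lipid droplet genes were higher on açai than on lingonberry, blackcurrant and bilberry, with 5, 6 and 4 of 14 called and 5, 7 and 6 adjusted over the list alone. Their adjusted p values were 0.0314, 0.00562 and 0.00125 with an estimated correlation, and the first was 0.055 without açai replicate 4. In fits on the arrays of the pair alone, an estimated correlation left calls for NRF2 targets (adjusted p = 0.0227) and lipid droplet genes (0.0327, 0.00645 and 0.0285). It left none for cholesterol synthesis (0.063 for lingonberry with 4 called, and 0.108 for blackcurrant with 1 called), the acute phase list (0.331 with 2 called, and 0.213 with no gene called for blackcurrant against bilberry, where 10 were called adjusted over the list alone) and fatty acid synthesis (0.1 with 7 called). Without the arrays of each chip in turn, cholesterol synthesis kept its calls in 3 and 4 of 6 fits, the acute phase list in 1 and 2, NRF2 targets in 4, fatty acid synthesis in 6 and lipid droplet genes in 3, 6 and 6.

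Against low fat, fatty acid oxidation genes and PPARα targets were higher on all 4 berry diets. On lingonberry, blackcurrant, bilberry and açai 11, 8, 9 and 12 of 22 were called higher and none lower, and 15, 14, 13 and 13 adjusted over the list alone. The adjusted p values were 0.00203, 0.0137, 0.0192 and 0.00834 with an estimated correlation. Fatty acid synthesis genes were lower than on low fat on lingonberry and blackcurrant, with 8 and 12 of 20 called and none higher, and 15 on each adjusted over the list alone. Their median was -0.65 on both diets, or -0.62 on lingonberry with undetected genes at their bounds, with adjusted p values of 0.00203 and 0.00121 with an estimated correlation. CAR and PXR targets were higher than on low fat on lingonberry (8 of 16 called, 14 adjusted over the list alone), bilberry (8 and 10) and açai (6 and 11, with 1 lower in the second count and with chip as a block). The adjusted p values were 0.000124, 0.000519 and 0.00444 with an estimated correlation. NRF2 targets were higher on lingonberry than on low fat, with 10 of 21 called, and 11 higher and 1 lower adjusted over the list alone (median 0.55, adjusted p = 0.00445 with an estimated correlation). Lipid droplet genes were higher on açai than on low fat, with 7 of 14 called higher and 1 lower, the same numbers adjusted over the list alone (median 0.65, adjusted p = 0.00444 with an estimated correlation). With only the arrays of the 2 diets fitted, the fatty acid oxidation list lost its call with an estimated correlation on all 4 berry diets (adjusted p = 0.0624, 0.111, 0.13 and 0.0857, with 7, 1, 5 and 10 called), as did fatty acid synthesis on blackcurrant (0.0661 with 8 called). The other lists of this paragraph kept theirs, with adjusted p values of at most 0.0498. Without the arrays of each chip fatty acid oxidation kept its call in 5 of 6 fits on blackcurrant and 4 on bilberry, and the other calls held in 6 of 6. The 4 berry diets were set against the same low-fat arrays, so that these results are not independent. High fat without berries also differed from low fat in the same direction in fatty acid oxidation, fatty acid synthesis and CAR and PXR targets. Differences from low fat in these lists therefore cannot be credited to the berries.

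The 974 control probes, which entered no comparison of the report, gave 0 calls with limma in each of the 6 comparisons. They were fitted as raw log2 intensities without background correction or normalization, so that brightness differences between arrays stayed in their spread. An unadjusted p below 0.05 was found for 1, 5, 5, 14, 6 and 5 of them, in the order high-fat, lingonberry, blackcurrant, bilberry, açai and açai against the other berries. These are shares below 0.05 throughout. The 0 calls are therefore no check of the normalized values. Deviations from the diet means correlated most on chip 3, with a median of 0.357 between its arrays, against 0.107 over all chips.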
